A study of Mus musculus with 32 samples.

How the data were processed

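RNA was sequenced from the microdissected dorsal hippocampus of 32 adult C57BL/6J mice, an inbred laboratory strain, with 1 library per animal. Lipopolysaccharide (LPS) is a component of the outer membrane of Gram-negative bacteria that activates innate immune cells through the receptor TLR4. Per the labels, pups were injected intraperitoneally on postnatal days 4 and 6 with LPS at 50 µg/kg or vehicle, received LPS at 50 µg/kg or vehicle again as adults, and gave tissue 4 h after the adult injection. The labels place the animals at postnatal days 87 to 91, whereas the protocol text places the adult injection on days 80 to 84, and the difference could not be settled from the sources used here. The 4 treatments (VEH/VEH, VEH/LPS, LPS/VEH and LPS/LPS) were each given to both sexes, which made 8 groups of 4 animals. They were read as neonatal/adult. The labels do not define this order in words, so it is inferred, and every neonatal and adult contrast rests on it. The 16 libraries with LPS in the second place were those set apart by the first principal component. Each animal number occurs in 1 group, so no pairing by animal was possible. Litter was not among the sample labels used here. Animals were treated as independent, and litters shared within a treatment could not be taken into account.

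The authors deposited raw counts, as whole numbers, for 55573 Ensembl genes in 32 libraries, without normalization. Libraries were made with an Illumina stranded mRNA kit per the labels. DRAGEN and the mm10 genome build were used per the submitters' processing notes; their roles, the DRAGEN version, the annotation release and whether counting used the strand are not given in the sources used here. Gene symbols were matched by Ensembl ID for 55394 genes, and the 179 without a symbol held 0.00891% of all counts. Coordinates, GC content and transcript length came from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 stands for. No library was left out of the reported fit. Library totals were 17947658 to 26602718 counts (median 20509639). The 48 pairs of replicates within groups differed by more than counting error, with a chi-square over degrees of freedom of 7.23 to 51.08, so no 2 libraries of the same group were copies of each other. Pairs across groups were not compared. Intervals on ratios and the lower bounds on folds cover counting error only.

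Genes were kept by filterByExpr with a minimum count of 10 and normalized by TMM in edgeR 4.0.16 under R 4.3.3. Of 55573 genes, 25742 had 0 counts in all libraries and 16548 were tested, 11 of them without a symbol. A quasi-likelihood model with 8 group means and robust dispersion was fitted to all 32 libraries, with 24 residual degrees of freedom, a median of 8.42 prior degrees of freedom and a common dispersion of 0.0312. Contrasts were adult LPS after neonatal vehicle, adult LPS after neonatal LPS, neonatal LPS with adult vehicle, neonatal LPS with adult LPS, and the neonatal by adult interaction. Each was tested over both sexes, in females, in males and as the difference between the sexes (male minus female), and the sexes were compared over all treatments. Tests were two-sided, with p values adjusted by the Benjamini-Hochberg method over all genes tested and a threshold of 0.05. Values are CPM (counts scaled to a common library size) with SD over animals, or log2 fold changes with SE. A fold over both sexes is the mean of the log2 changes of the sexes, so it can differ from the ratio of the pooled means. The SE is the log2 fold change over the square root of its quasi-likelihood F statistic. The SEs of a gene in different contrasts need not be on the same scale or add up, as for Cxcl10. Where the control group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% counting interval. Genes of the fixed lists below the filter that held at least 10 counts, 35 in all, were compared between adult LPS and adult vehicle by a permutation test with 100000 draws. The result of 1 of these genes is not reported here.

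Before the data were examined, 37 gene lists, all contrasts and the rule for named genes were fixed. The response lists were NF-kB targets, cytokines and chemokines; interferon-stimulated genes; antigen presentation by MHC class I; complement; reactive astrocyte genes; endothelial activation; homeostatic microglia; activated microglia and phagocytes; glucocorticoid-responsive genes; steroid synthesis and metabolism enzymes; steroid receptors and cochaperones; cholesterol synthesis; activity-dependent immediate early genes; circadian clock; heat shock and unfolded protein response; glutamate and GABA receptors; and tight junctions and barrier transport. The cell type lists were markers of endothelial cells, pericytes and smooth muscle, oligodendrocytes, oligodendrocyte precursors, astrocytes, GABAergic neurons, dentate gyrus granule cells, CA1 pyramidal cells, CA2 and CA3 pyramidal cells, thalamus, neocortex, choroid plexus, ependymal cells, meningeal and perivascular fibroblasts, neutrophils and monocytes, lymphocytes, and blood erythroid cells. Mitochondrially encoded mRNA, nuclear-encoded oxidative phosphorylation and cytosolic ribosomal proteins served as signs of RNA quality. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and with fry, and list p values were adjusted over the 36 lists with at least 5 tested members. Some genes belong to more than 1 list, among them Nfkbia, Fkbp5, Gjb6, Cebpd and Hspb1.

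The rule named, for each contrast over both sexes and for sex, the 10 largest positive and 10 largest negative log2 fold changes among genes past the threshold with the same sign in both sexes and a mean of at least 1 CPM. It added up to 4 members of each list with the smallest p and, where fewer than 5 genes passed, the 5 with the smallest p. For each contrast within a sex and for each sex difference it took the 5 smallest p. Xist, Kdm5d, Eif2s3y, Uty, Ddx3y, Lcn2, Il1b, Tnf, Ccl2, Cxcl10, Nfkbia, Fkbp5, Tsc22d3, Tspo, Hsd11b1 and Nr3c1 were always included. Predicted and RIKEN clone genes were counted but left out of these rankings and not named, except Gm12715, which was chosen after its values were seen.

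The fits were tested on simulated data with known changes. At a true change of 1.5-fold and 2-fold, the fit for adult LPS after neonatal vehicle recovered 61.6% and 78.8% of changed genes over both sexes and 46.5% and 65.3% in females. The same changes were recovered at 61.2% and 83% for neonatal LPS with adult vehicle, at 31.3% and 65% for the interaction, and at 20% and 50.5% for a difference between the sexes. Between 0 and 6 unchanged genes were called per fit, and 4.65% to 5.05% of unchanged genes had an unadjusted p under 0.05. In the data, smaller shares of the 16548 genes had one for the interaction (397), neonatal LPS with adult vehicle (672) and the sex difference of adult LPS after neonatal vehicle (511). Recovery in these contrasts may therefore be lower than simulated. Camera called the changed list with the preset and with the estimated correlation and 0 of 35 unchanged lists with either. The simulated genes were drawn independently, and the unchanged lists at random. This does not show how often lists of correlated genes are called wrongly. With the preset correlation, other splits of the real libraries called many lists, as given below.

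Alternatives fixed at the start were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, RIN (a score of RNA integrity) as a covariate, library date as a covariate, a covariate for library names ending in -R, those libraries left out, a fit to the groups of a contrast alone, the estimated correlation for lists, and each of the 32 animals left out in turn. Chosen after seeing the data were a term for 8 libraries set apart by the second principal component, those 8 left out, the level of Ttr (a choroid plexus transcript) as a covariate, and a neonatal contrast averaged over adult treatments. Ttr is itself a member of the choroid plexus list. A Ttr covariate therefore takes out signal of that list whatever its cause, and the loss of its call there decides nothing. Principal components used log2 CPM with a prior count of 2. Figures were drawn with matplotlib 3.10.9.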

Results

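Gene expression was measured in 32 libraries from the dorsal hippocampus, 1 per mouse, in 8 groups of 4 animals formed by neonatal treatment, adult treatment and sex. Treatments are read as neonatal/adult, an order inferred and not defined in the labels, so VEH/LPS stands for vehicle as a pup and lipopolysaccharide (LPS) as an adult. Library totals ran from 17947658 to 26602718 counts with a median of 20509639. Group means ran from 19313263 ± 1070965 counts (SD, n = 4) in VEH/LPS males to 23225759 ± 3114391 counts (SD, n = 4) in LPS/LPS males. Each library had counts for 18850 to 21142 genes, RIN was 7.7 to 9.9, and mitochondrially encoded genes took 1.74% to 6.13% of counts. The first principal component, 19.8% of the variance, placed the 16 adult LPS libraries at 21.25 to 36.33 and the 16 adult vehicle libraries at -32.75 to -22.96.

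The second component, 10.4% of the variance, set 8 libraries apart at -38.84 to -24.32, whereas the other 24 lay at -3.92 to 33.09. These are the 6 libraries with names ending in -R and the 2 without a date, and the meaning of the ending is not given in the sources used here. Of the 8, 4 were VEH/VEH, 2 were VEH/LPS, 1 was LPS/VEH and 1 was LPS/LPS. In a fit with a term for them, 1625 genes were higher and 1372 lower in these libraries, 28 and 323 of them by at least 2-fold. Counts for the comparisons below are therefore also given without them.

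**Figure D1:**
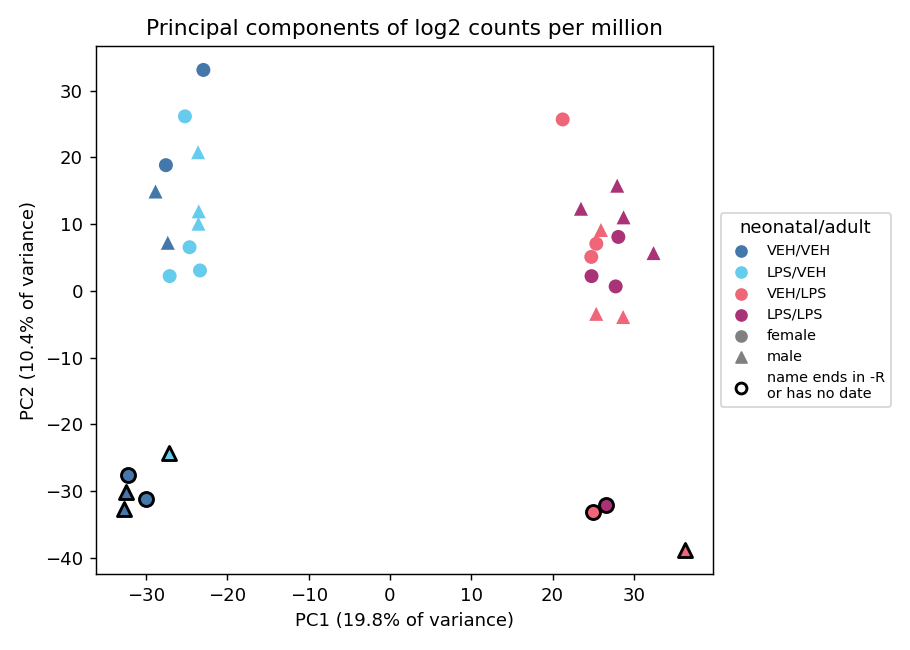
Each point is 1 of the 32 libraries on the first component (x, 19.8% of variance) and the second (y, 10.4%) of log2 CPM, with colour for treatment and shape for sex. Adult LPS libraries lie at 21.25 to 36.33 on x, and the 8 ringed libraries lie at -38.84 to -24.32 on y.

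The first comparison asked how the hippocampus of adults treated with vehicle as pups differed 4 h after LPS (VEH/LPS against VEH/VEH, 8 animals each). Interferon-stimulated, cytokine and antigen presentation genes rose together, while transcripts of brain endothelial cells and their tight junctions fell. Rsad2 (ENSMUSG00000020641; GRCm38 chromosome 12, 26442746 to 26456452), an antiviral enzyme induced by interferon, rose from 1.295 ± 0.5679 to 138 ± 35.7 CPM (SD, n = 8 each; log2 fold change 6.74 ± 0.21 SE, adjusted p = 5.86e-20). Cxcl10 (ENSMUSG00000034855; chromosome 5, 92346638 to 92348889), a chemokine that attracts T cells, rose from 0.221 ± 0.246 to 65.6 ± 16.1 CPM (log2 8.53 ± 0.36, adjusted p = 3.53e-16). Cldn5 (ENSMUSG00000041378; chromosome 16, 18776847 to 18778262), the main claudin of the blood-brain barrier, went from 46.7 ± 6.19 to 8.40 ± 2.65 CPM (log2 -2.47 ± 0.14, adjusted p = 1.68e-14). Each of the 3 lay beyond every vehicle animal of the same sex in 8 of 8 LPS animals. In all, 592 genes were higher and 296 lower, 317 and 85 of them by at least 2-fold, and 2061 had an unadjusted p under 0.05. With the 8 libraries left out, 667 genes passed, 619 of them among the 888.

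Of the 35 tested interferon-stimulated genes, 33 rose and 0 fell, and 34 rose when adjusted over the list alone. They included the guanylate-binding proteins Gbp2 (145 ± 16.99 CPM against 4.00 ± 1.85, log2 5.24 ± 0.18) and Gbp5 (log2 4.94 ± 0.15), and Ifit3 (log2 4.01 ± 0.14). Of 25 NF-kB targets, cytokines and chemokines, 21 rose, and all 25 did so adjusted over the list alone. Icam1, an adhesion molecule for leukocytes, rose from 2.71 ± 0.971 to 27.1 ± 7.96 CPM (log2 3.36 ± 0.22), and Nfkbia, the inhibitor that NF-kB itself induces, from 17.6 ± 2.24 to 48.3 ± 5.44 CPM (log2 1.46 ± 0.09). The chemokine Ccl2 rose by a log2 of 5.71 ± 0.78 (4.93 without VEH/LPS male 8, 7.13 without VEH/VEH male 24 and 6.37 without VEH/VEH female 27). Il1b had 2 counts in the 8 vehicle libraries, both in VEH/VEH male 1, a ratio of 116 with a counting interval of 31.8 to 965. Cxcl9 and Il1rn had 0 counts there and were at least 156-fold and at least 224-fold higher, against a floor of 3 counts over the group. For Il1rn the bound was 115 without VEH/LPS male 8. Of 16 genes of antigen presentation by MHC class I, 12 rose, 14 adjusted over the list alone, with the peptide transporter Tap1 at a log2 of 2.78 ± 0.12, the class I gene H2-Q4 at 2.48 ± 0.15 and the immunoproteasome subunit Psmb8 at 1.54 ± 0.12.

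Vascular genes moved both ways. Of 15 genes of tight junctions and barrier transport, 8 fell and 1 rose, 10 and 1 adjusted over the list alone, among them the transporter Slco1a4 (log2 -1.61 ± 0.12), the tricellular junction receptor Lsr (-1.58 ± 0.14) and the efflux pump Abcb1a (-0.88 ± 0.09). Of 14 endothelial cell markers, 8 fell and 1 rose, 8 and 3 adjusted over the list alone. The angiopoietin receptor Tek (-1.94 ± 0.15) and the VEGF receptor Kdr (-1.61 ± 0.10) fell, and the adherens junction cadherin Cdh5 rose (1.05 ± 0.11). Among the largest falls outside the lists were Degs2, a sphingolipid desaturase and hydroxylase (0.113 ± 0.0925 CPM against 3.27 ± 0.716, log2 -4.90 ± 0.37), Sox17, an endothelial transcription factor (-2.45 ± 0.24), and Hspa12b (-2.31 ± 0.16). Of 25 endothelial activation genes, 16 rose and 1 fell, 18 and 2 adjusted over the list alone, with Il4ra at 2.92 ± 0.14, Plaur, the urokinase receptor, at 3.06 ± 0.33, and Ch25h, which makes 25-hydroxycholesterol, at 5.45 ± 0.43. The selectin Sele had 0 counts in VEH/VEH and was at least 74.4-fold higher against the same floor. Of 12 markers of pericytes and smooth muscle, 0 passed, alone or over all genes (list adjusted p = 0.0464, lower; adjusted p = 0.534 with an estimated correlation). With 1 animal left out in turn the list's adjusted p was 0.006 to 0.118, and 10 of the 32 ended the call.

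Genes that respond to glucocorticoids rose as a group: 18 of 22 rose and 0 fell, 20 adjusted over the list alone. Tsc22d3, which encodes the mediator GILZ, rose from 30.9 ± 5.26 to 78.5 ± 15.8 CPM (log2 1.35 ± 0.12, adjusted p = 5.16e-10), Cdkn1a, a cell cycle inhibitor, from 9.19 ± 1.40 to 50.4 ± 8.14 CPM (2.46 ± 0.13), and Fkbp5, a cochaperone that dampens the glucocorticoid receptor, from 84.5 ± 9.82 to 131 ± 15.4 CPM (0.63 ± 0.08, adjusted p = 2.61e-07). Of 17 steroid receptors and cochaperones, 1 rose (Fkbp5) and 1 fell, with the same counts adjusted over the list alone. The gene that fell was Nr3c1, the glucocorticoid receptor, at 56.6 ± 6.94 CPM against 75.6 ± 8.59 (-0.42 ± 0.09, adjusted p = 0.000835, lower in 8 of 8; over the alternatives adjusted p = 3.9e-05 to 0.056, the highest without the libraries with names ending in -R). Of 20 steroid synthesis and metabolism enzymes, 0 passed, also adjusted over the list alone. Among them the mitochondrial protein Tspo differed by 0.13 ± 0.15 (adjusted p = 0.889) and Hsd11b1, which regenerates corticosterone, by 0.03 ± 0.08 (adjusted p = 0.977).

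Glial lists differed in direction. Of 26 reactive astrocyte genes, 10 rose and 2 fell, 12 and 2 adjusted over the list alone. Lcn2 (ENSMUSG00000026822; chromosome 2, 32384633 to 32388252), an iron-sequestering protein of the acute phase, rose from 0.283 ± 0.485 to 75.4 ± 47.6 CPM (log2 8.14 ± 0.73), and the oncostatin M receptor Osmr rose by 2.33 ± 0.17. The VEH/VEH mean of Lcn2 was 0.12 CPM without male 23, where the log2 fold change was 9.38, and it was 8.77 without VEH/VEH female 26. Of 21 genes of activated microglia and phagocytes, 8 rose and 0 fell, 10 adjusted over the list alone, such as the Fc receptors Fcgr3 (1.37 ± 0.10) and Fcgr1 (1.00 ± 0.13). Of 16 homeostatic microglia genes, 7 fell and 0 rose, 8 and 1 adjusted over the list alone (list adjusted p = 2.96e-05, lower; adjusted p = 0.184 with an estimated correlation). The fractalkine receptor Cx3cr1 fell from 63.0 ± 9.08 to 37.04 ± 9.25 CPM (-0.80 ± 0.10) and the purine receptor P2ry12 by a log2 of 0.72 ± 0.12. Of 14 complement genes, 5 rose and 0 fell, also adjusted over the list alone, with the anaphylatoxin receptors C5ar1 at 3.58 ± 0.22 and C3ar1 at 1.35 ± 0.21. C1qa (0.35 ± 0.09) and C1qb (0.35 ± 0.09) passed with all libraries. Over the alternatives their adjusted p ran from 0.00078 to 0.49 and from 0.0027 to 0.64, the highest without the libraries with names ending in -R.

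Neuronal, clock, stress and metabolic lists were tested in the same way. Of 25 activity-dependent immediate early genes, 6 fell and 1 rose, 9 and 3 adjusted over the list alone (list adjusted p = 0.0073, lower; adjusted p = 0.243 with an estimated correlation). Egr1 fell from 134 ± 42.4 to 75.2 ± 10.5 CPM (-0.84 ± 0.16) and Inhba by a log2 of 0.95 ± 0.16, and the stress-inducible Gadd45g rose (1.43 ± 0.18). Of 17 circadian clock genes, 2 fell (Per2, Cry2) and 1 rose (Nfil3), 3 and 2 adjusted over the list alone. Over the alternatives adjusted p ran from 6e-04 to 0.077 for Per2 and from 0.00031 to 0.1 for Cry2, the highest without the 8 libraries, and from 0.0096 to 0.37 for Nfil3, the highest without those with names ending in -R. Their calls ended in 1, 2 and 12 of 43 alternatives. Of 22 heat shock and unfolded protein response genes, 1 fell, also adjusted over the list alone (Pdia6, -0.30 ± 0.08; over the alternatives adjusted p = 0.0014 to 0.14, the highest without the libraries with names ending in -R). Among 35 glutamate and GABA receptors and 23 cholesterol synthesis genes, 0 passed over all genes or adjusted over the list alone.

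Markers of other cells and of RNA quality were read beside these groups. None of the 14 oligodendrocyte, 15 GABAergic, 11 dentate granule, 8 CA1, 11 CA2 and CA3, 13 fibroblast or 6 erythroid markers passed in edgeR over all genes or adjusted over the list alone. Single markers passed among 10 oligodendrocyte precursor genes (Sox10, -0.51 ± 0.15), 11 thalamus genes (Rgs16, 1.02 ± 0.23), 8 ependymal genes (Tekt4, 1.51 ± 0.43) and 17 choroid plexus genes (Cldn1, -2.62 ± 0.68), and adjusted over the list alone 1 ependymal gene was also lower. Over the alternatives adjusted p ran from 0.006 to 0.12 for Sox10 (highest without VEH/VEH female 26), from 0.0034 to 0.17 for Tekt4 (highest with a covariate for names ending in -R) and from 0.00064 to 0.2 for Cldn1 (highest without the 8 libraries, log2 -3.23 without VEH/LPS male 28). Their calls ended in 13, 6 and 2 of 43 alternatives. The choroid plexus list, 5 lower adjusted over the list alone, was lower (adjusted p = 0.00794; adjusted p = 0.89 with an estimated correlation). Without VEH/VEH female 27, which had 789.2 CPM of the choroid plexus transcript Ttr, the list stood at adjusted p = 0.0922, and with a Ttr covariate at 0.0678. Because Ttr is in this list, the covariate takes out part of its signal whatever the cause. None of 10 neocortex genes passed. Of 14 astrocyte markers, 2 rose (Gjb6, 0.50 ± 0.08, and Fgfr3, 0.29 ± 0.07; for Fgfr3 adjusted p = 0.003 to 0.27 over the alternatives, the highest without the 8 libraries). Of 10 neutrophil and monocyte markers, 6 rose, 7 adjusted over the list alone (list adjusted p = 0.000113; adjusted p = 0.179 with an estimated correlation). Among them S100a8 stood at 2.64 ± 5.51 CPM against 0.0736 ± 0.126 (adjusted p = 0.00299, higher in 7 of 8; over the alternatives adjusted p = 0.00023 to 0.2, the highest without the libraries with names ending in -R). VEH/LPS male 8 alone had 16.22 CPM. Without it the mean of S100a8 was 0.702 CPM and the log2 fold change 3.09 (adjusted p = 0.011), and without VEH/VEH male 23 the log2 fold change was 5.26. None of 11 mitochondrially encoded, 39 oxidative phosphorylation or 44 ribosomal protein genes passed, also adjusted over the list alone. As lists in camera with the preset correlation, oxidative phosphorylation and ribosomal proteins were not called (adjusted p = 0.202 and 0.0567). With a term for the 8 libraries both were lower (0.00404 and 0.00214), and without the 8 neither was called (0.208 for each).

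The second comparison put the same question to animals given LPS as pups (LPS/LPS against LPS/VEH, 8 animals each). Interferon-stimulated, cytokine and glucocorticoid-responsive genes rose, and barrier genes fell. Rsad2 rose from 1.34 ± 0.373 to 129 ± 36 CPM (SD, n = 8 each; log2 6.58 ± 0.20 SE, adjusted p = 1.32e-19), and Cxcl10 from 0.219 ± 0.201 to 61.8 ± 19.9 CPM (8.16 ± 0.35, adjusted p = 4.88e-16). Cldn5 went from 49.7 ± 8.20 to 9.71 ± 1.89 CPM (-2.35 ± 0.14, adjusted p = 4.49e-14), and Tsc22d3 rose from 30.4 ± 3.94 to 83.8 ± 15.3 CPM (1.46 ± 0.12, adjusted p = 9.75e-11). Each lay beyond every control of the same sex in 8 of 8 animals. In all, 648 genes were higher and 288 lower, 317 and 83 by at least 2-fold, and 2000 had an unadjusted p under 0.05. With the 8 libraries left out, 885 genes passed, 814 of them among the 936.

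Of the interferon-stimulated genes, 33 of 35 rose, 34 adjusted over the list alone, with Gbp2 at 153 ± 22.6 CPM against 4.86 ± 1.07 (4.97 ± 0.18) and Ifit3 at 3.59 ± 0.14. Of the NF-kB targets, cytokines and chemokines, 22 of 25 rose, 23 adjusted over the list alone. Nfkbia rose by 1.63 ± 0.09, Icam1 by 3.31 ± 0.22, Ccl2 by 5.52 ± 0.79 and Il1b by 3.05 ± 0.67 (higher in 6 of 8). Cxcl9 had 0 counts in LPS/VEH and was at least 184-fold higher, against a floor of 3 counts over the group. Of the MHC class I genes, 12 of 16 rose, 14 adjusted over the list alone, with Tap1 at 2.40 ± 0.11. Of 14 complement genes, 5 rose, also adjusted over the list alone, among them C5ar1 (3.76 ± 0.22) and C1qb (0.41 ± 0.09). Of 26 reactive astrocyte genes, 14 rose and 0 fell, 15 and 1 adjusted over the list alone, with Osmr at 1.97 ± 0.16 and Tm4sf1 at 1.19 ± 0.13. Lcn2 rose from 4.97 ± 8.66 to 87.2 ± 27.5 CPM (5.93 ± 0.63, the mean of the log2 changes of the sexes). The control mean rests on LPS/VEH males 2 and 25, at 15.92 and 21.62 CPM, whereas the other 6 animals had 0 to 0.9805. Lcn2 went from 9.731 to 104.9 CPM in males (3.44 ± 0.67) and from 0.2055 to 69.45 CPM in females (8.42 ± 1.06), a difference that did not pass (-4.98 ± 1.38, adjusted p = 1). For Lcn2 the value was 4.19 in males without LPS/VEH male 25 and 10.32 in females without LPS/VEH female 31, and over both sexes 6.88 without female 31. The call of Lcn2 in males ended in a fit to the groups of that contrast alone (adjusted p = 0.00069 to 0.25 over the alternatives). Of 21 genes of activated microglia and phagocytes, 8 rose and 1 fell, 11 and 1 adjusted over the list alone, with Fcgr3 at 1.65 ± 0.10. Of 16 homeostatic microglia genes, 7 fell and 1 rose, 7 and 3 adjusted over the list alone (list adjusted p = 0.00102, lower; adjusted p = 0.343 with an estimated correlation), with Cx3cr1 at -0.95 ± 0.10.

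Of the endothelial activation genes, 15 of 25 rose and 1 fell, 18 and 1 adjusted over the list alone, with Il4ra at 2.999 ± 0.14. Of the tight junction and barrier transport genes, 9 of 15 fell and 1 rose, also adjusted over the list alone, with Slco1a4 at -1.67 ± 0.12 and Abcb1a at -1.04 ± 0.09. Of 14 endothelial markers, 7 fell and 1 rose, 8 and 2 adjusted over the list alone, with Tek at -2.03 ± 0.15 and Cdh5 at 1.11 ± 0.11. Degs2 fell from 3.58 ± 0.605 to 0.370 ± 0.260 CPM (-3.37 ± 0.31). Of 22 glucocorticoid-responsive genes, 19 rose and 0 fell, 20 adjusted over the list alone, with Cdkn1a at 2.50 ± 0.13 and Fkbp5 at 140 ± 12.3 CPM against 92.7 ± 15.9 (0.60 ± 0.08). Of 17 steroid receptors and cochaperones, Fkbp5 rose and Nr3c1 fell, and 1 rose and 2 fell adjusted over the list alone. Nr3c1 stood at 59.2 ± 9.13 CPM against 72.0 ± 9.26 (-0.28 ± 0.09, adjusted p = 0.0425, lower in 6 of 8; over the alternatives adjusted p = 0.004 to 0.17, the lowest without LPS/LPS male 3 and the highest without LPS/VEH male 9, and 23 of 43 alternatives ended the call). Of 20 steroid synthesis and metabolism enzymes, 0 passed, also adjusted over the list alone, with Tspo at 0.34 ± 0.15 (adjusted p = 0.303) and Hsd11b1 at 0.09 ± 0.08 (adjusted p = 0.83).

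Of 25 immediate early genes, 6 fell and 1 rose, 6 and 2 adjusted over the list alone (list adjusted p = 0.00216, lower; adjusted p = 0.187 with an estimated correlation), with Bdnf, a neurotrophin, at -0.61 ± 0.08 and Npas4 at -1.94 ± 0.39. Of 17 clock genes, Per2 (-0.39 ± 0.09) and Cry2 (-0.27 ± 0.05) fell and Bhlhe40 rose (0.46 ± 0.13, over the alternatives adjusted p = 0.0055 to 0.2, the highest without the 8 libraries), with the same counts adjusted over the list alone. The call of Bhlhe40 ended in 12 of 43 alternatives. Of 22 heat shock and unfolded protein response genes, 2 rose, 3 adjusted over the list alone, with Hspb1 at 0.81 ± 0.16. Astrocyte markers were higher as a list (adjusted p = 0.000197; adjusted p = 0.188 with an estimated correlation), and 2 of 14 rose, 4 adjusted over the list alone. Of 10 neutrophil and monocyte markers 1 rose, 4 adjusted over the list alone (list adjusted p = 0.0129; adjusted p = 0.461 with an estimated correlation). That gene was S100a8, at 1.09 ± 1.74 CPM against 0.0620 ± 0.0690 (adjusted p = 0.0262, over the alternatives adjusted p = 0.004 to 0.072, the highest with no filter on low counts). Its call ended in 10 of the 42 alternatives with a value for it. The mean of S100a8 in LPS/LPS was 0.53 CPM without male 14, which had 5.043. Single markers also rose among precursors of oligodendrocytes (Neu4, 0.50 ± 0.11), thalamus (Rgs16, 0.74 ± 0.23), neocortex (Ccn2, 1.24 ± 0.29) and fibroblasts (Mgp, 0.58 ± 0.18). Over the alternatives adjusted p ran from 6e-04 to 0.13 for Rgs16 (highest without LPS/VEH male 2) and from 0.0068 to 0.14 for Mgp (highest without the 8 libraries). The calls of Rgs16 and Mgp each ended in 28 of 43 alternatives. In edgeR over all genes, 0 genes passed in the receptor, cholesterol, pericyte, oligodendrocyte, GABAergic, dentate, CA1, CA2 and CA3, choroid plexus, ependymal, erythroid and RNA quality lists, also adjusted over the list alone.

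With camera's preset correlation, 15 lists were called after neonatal vehicle and 14 after neonatal LPS. The calls that hold with an estimated correlation are the same 10 in both: NF-kB targets, interferon-stimulated genes, MHC class I, complement, reactive astrocyte genes, endothelial activation, activated microglia, glucocorticoid-responsive genes, tight junctions and barrier transport, and endothelial cells. Without the 8 libraries the complement list stood at adjusted p = 0.0565 after neonatal vehicle, with the preset correlation. In each list called, the median, the mean and the test had the same sign. The lymphocyte list had too few genes past the count filter to be tested as a list. Among its members Cd8a, a marker of cytotoxic T cells, had 4 counts over the 16 adult LPS libraries, all in VEH/LPS female 19, and 25 over the 16 adult vehicle libraries, 12 of them in VEH/VEH female 20 (two-sided permutation test, p = 0.072, adjusted p = 0.264).

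**Figure D2:**
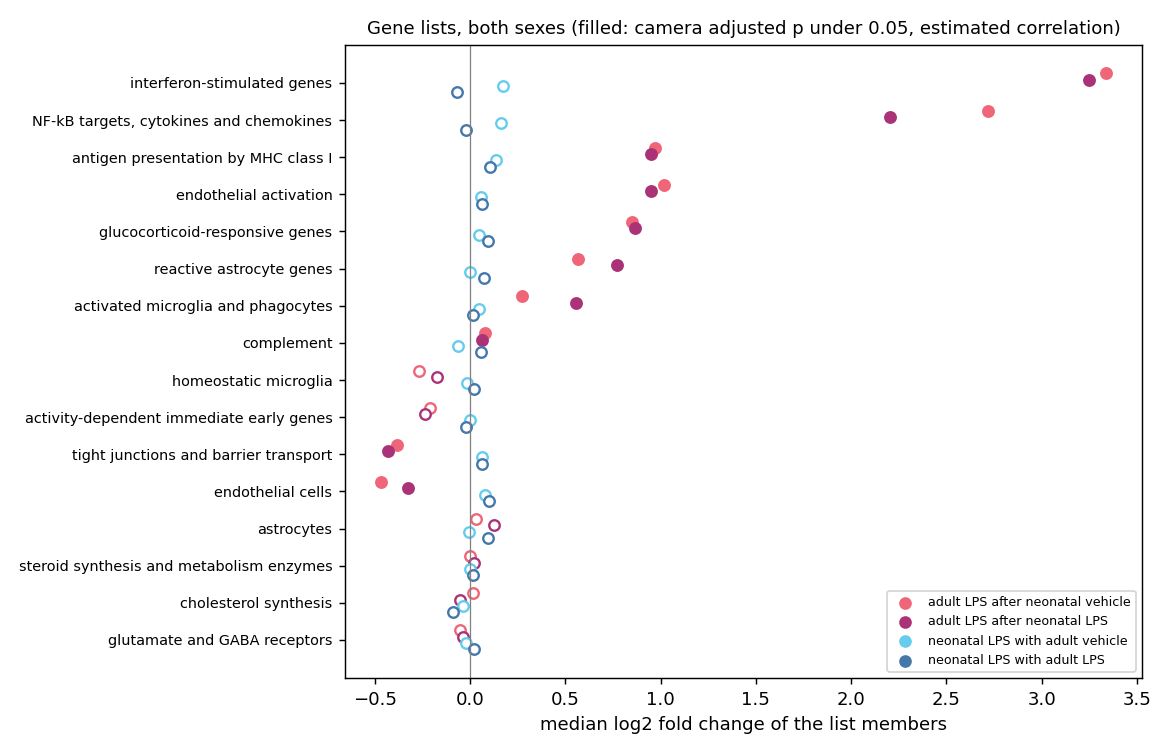
Each point is the median log2 fold change (x) of the tested members of 1 fixed list (y), coloured by contrast over both sexes and filled where the camera adjusted p was under 0.05 with an estimated correlation. Setting genes with 0 control counts at their lower bound left these medians the same, and 10 lists are filled for each adult LPS contrast and 0 for each neonatal LPS contrast.

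The next question was whether LPS given to pups changed the adult response. For single genes the difference between the responses (interaction) did not pass the test: it was -0.37 ± 0.80 for Cxcl10, 0.11 ± 0.17 for Tsc22d3 and -0.03 ± 0.11 for Fkbp5 on the log2 scale (SE, 8 animals in each of 4 treatments). The SE of Cxcl10 is larger here than those of its adult LPS contrasts would give. Each SE comes from its own F statistic, and the vehicle groups had 34 and 35 counts of this gene. Both contrasts called 500 genes higher (23.2 expected if the calls were independent) and 205 lower (5.2 expected). Of these 705, 347 had the larger response after neonatal LPS, the median difference was -0.002, and 19 had an unadjusted interaction p under 0.05. Over the 1119 genes called in either contrast the fold changes had r = 0.961, and over all tested genes r = 0.728, with genes not independent replicates. A further 414 genes were called in 1 contrast and not in the other, and 0 of them passed the interaction test. The interaction called 0 genes in edgeR (397 at unadjusted p under 0.05) and 0 in DESeq2, and its 95% interval lay within 1 log2 unit of 0 for 77.6% of genes. These 397 are a smaller share of the 16548 genes than the 4.92% of unchanged genes in the simulation. The test may therefore recover fewer changes here than simulated. Predicted and RIKEN genes aside, those with the smallest p, none past the threshold (adjusted p = 1), were Gng5 (0.63 ± 0.15), Mgst1 (0.58 ± 0.15), Ninl (-0.82 ± 0.24), Myct1 (-2.89 ± 0.85; -3.67 without LPS/LPS female 17) and Wfdc2 (8.03 ± 2.13; 6.07 without LPS/LPS female 22). The values of the last pair rest on few counts. Myct1 had 8 counts over the 8 LPS/LPS libraries, and Wfdc2 had 1 count over the 8 VEH/LPS libraries. Of the 90 Wfdc2 counts in LPS/LPS, 57 were in male 21, and of the 92 in VEH/VEH, 59 were in female 27. These animals also had the most Ttr of their treatments, 1328 and 789.2 CPM.

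**Figure D3:**
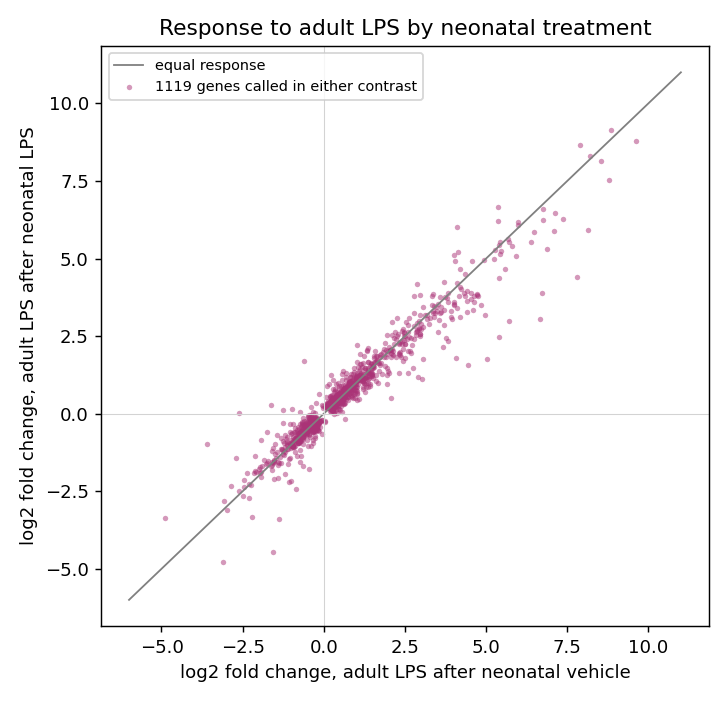
Each point is 1 of the 1119 genes called in either adult LPS contrast, with its log2 fold change after neonatal vehicle (x) and after neonatal LPS (y), both sexes, and the line marks equal responses. Across these genes r = 0.961, and 0 genes passed the test of the difference.

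As lists, the interaction was lower for interferon-stimulated genes (adjusted p = 0.00126; adjusted p = 0.933 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. It was higher for the choroid plexus list (adjusted p = 5e-07; adjusted p = 0.933 with an estimated correlation), with 12 of 17 members higher adjusted over the list alone. Ttr, a member of that list, reached 1328 CPM in LPS/LPS male 21, 825.3 in LPS/LPS female 22 and 789.2 in VEH/VEH female 27. The list stayed higher with 1 animal left out (adjusted p = 2.66e-10 to 0.000563) and stood at adjusted p = 0.275 with a Ttr covariate. Neither decides the cause. High Ttr was found in more than 1 animal, so leaving out 1 at a time cannot remove it. The covariate is itself a member of the list. A different mix of cells, with uneven amounts of choroid plexus among the samples, is therefore not excluded. Heat shock (adjusted p = 0.0109), pericyte (0.0486), astrocyte (0.00805), mitochondrially encoded (0.00013), oxidative phosphorylation (0.0127) and ribosomal protein genes (0.003) were also higher with the preset correlation. Each of the 6 stood at adjusted p = 0.933 with an estimated correlation and held 0 genes past the threshold adjusted over the list alone. With 1 animal left out in turn, 2 of the 8 list calls, the choroid plexus and the mitochondrially encoded genes, held each time. The interferon call ended without VEH/LPS male 8 (adjusted p = 0.0508), and the pericyte call ended with 19 of the 32 left out. The 8 libraries, 4 of them VEH/VEH, bear on these lists. VEH/VEH adds to the interaction, so genes higher in these libraries would raise it. Mitochondrially encoded genes are higher in them (7 of 11), the direction of that call. Oxidative phosphorylation (20 of 39) and ribosomal protein genes (12 of 44) are lower in them, which would lower the interaction, against the direction of their calls. With a term for the 8 libraries and without them the mitochondrially encoded list stood at adjusted p = 0.00789 and 0.0575, the interferon list at 3.97e-06 and 0.219, the pericyte list at 0.0703 and 0.00352 and the astrocyte list at 0.0654 and 0.004. The choroid plexus, heat shock, oxidative phosphorylation and ribosomal protein lists stayed called in both.

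Neonatal LPS without an adult challenge (LPS/VEH against VEH/VEH, 8 animals each) asked for a lasting change at baseline. None of the genes fixed for the treatment passed the test: Cxcl10 differed by a log2 of 0.28 ± 0.77, Nfkbia by -0.08 ± 0.09, Tsc22d3 by -0.02 ± 0.12 and Nr3c1 by -0.07 ± 0.09 (72.0 ± 9.26 CPM against 75.6 ± 8.59, SD, n = 8 each). Predicted and RIKEN genes aside, the smallest p values belonged to Phf21b (5.06 ± 0.946 CPM against 3.55 ± 0.580, log2 0.52 ± 0.14), Ppp1r15a (0.38 ± 0.10), Srsf1 (-0.30 ± 0.08), Purg (-0.43 ± 0.11) and Tmem267 (-0.75 ± 0.19), at adjusted p = 1. In edgeR 0 genes passed (672 at unadjusted p under 0.05), and 0 in DESeq2. The 95% interval excluded a 2-fold change for 85.7% of genes. With the preset correlation the interferon list (adjusted p = 0.0176), the MHC class I list (0.000199; 2 members higher adjusted over the list alone) and endothelial markers (0.0253) were higher. Heat shock genes (0.0105), choroid plexus (0.0105) and mitochondrially encoded genes (0.0102) were lower. All 6 had adjusted p = 0.94 with an estimated correlation. With 1 animal left out in turn, the MHC class I and mitochondrially encoded lists stayed called each time. The 8 libraries, in which mitochondrially encoded genes are higher, include 4 of VEH/VEH and 1 of LPS/VEH. The mitochondrially encoded call ended with a term for them, where its direction turned (higher, adjusted p = 0.784), and without them (lower, 0.768). Without them, with fewer samples, the MHC class I (0.329) and interferon (0.106) calls also ended, as did the endothelial call, whose direction turned (lower, 0.736). With the term these 3 held (1.05e-05, 1.05e-05 and 0.0381), but they did not move alone, since 13 lists were called in that fit. The choroid plexus list stood at adjusted p = 0.257 without VEH/VEH female 27, and its call also ended without VEH/VEH males 23 and 34, VEH/VEH female 26 or LPS/VEH male 35. With a covariate for Ttr, itself a member of the list, its direction turned (adjusted p = 0.694), which does not tell the cause. The interferon call ended with 5 animals left out, each in turn (highest adjusted p = 0.076), the endothelial call with 6 (0.266) and the heat shock call with 3 (0.145).

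Neonatal LPS followed by adult LPS (LPS/LPS against VEH/LPS, 8 animals each) asked the same under challenge. Predicted and RIKEN genes aside, those with the smallest p were H2-Q6, a class I gene (10.3 ± 3.13 CPM against 5.15 ± 2.35, SD, n = 8 each; log2 1.02 ± 0.24), Degs2 (1.67 ± 0.45), Ctla2a (0.95 ± 0.26), Ampd3 (0.28 ± 0.07) and Smim5 (3.03 ± 0.81; 3.69 without VEH/LPS female 30), at adjusted p = 0.999. In edgeR 0 genes passed (703 at unadjusted p under 0.05), and 0 in DESeq2. The interval excluded a 2-fold change for 85.4% of genes. With the preset correlation 13 lists were called, 10 higher and 3 lower, and 0 of them with an estimated correlation, where the smallest adjusted p was 0.411. The MHC class I list (adjusted p = 5.8e-05; 1 member higher adjusted over the list alone) and the glucocorticoid list (0.000801; 0 members) were higher, each at adjusted p = 0.411 with an estimated correlation. Lists of anatomical markers differed beside these. The choroid plexus list was higher (adjusted p = 0.00142, 9 members higher adjusted over the list alone; adjusted p = 0.797 with an estimated correlation). Ttr, one of its members, stood at 1328 CPM in LPS/LPS male 21 and 825.3 in LPS/LPS female 22, against 1.21 to 56.87 and 0.4323 to 2.032 in their group mates. The list call ended without male 21 (adjusted p = 0.115) and without female 22 (0.161). It also ended with a Ttr covariate (0.0547), which decides nothing since Ttr is in the list. CA1 markers were also higher (0.00465; 0.713 with an estimated correlation), a call that ended without VEH/LPS male 28 (0.178). CA2 and CA3 markers (0.00465) and thalamus markers (0.00804) were lower, at adjusted p = 0.579 and adjusted p = 0.713 with an estimated correlation. The first call ended without LPS/LPS male 3 (0.0551), and the thalamus call without VEH/LPS male 28 or female 30 (highest 0.104). Of the other lists called, astrocyte (0.00139), pericyte (0.00387), endothelial (0.00465), tight junction (0.0222) and oligodendrocyte precursor (0.0336) lists were higher and cholesterol synthesis (0.0017) lower. Cytosolic ribosomal proteins, a sign of RNA quality, were higher too (0.00948; adjusted p = 0.889 with an estimated correlation), a call that ended with 5 animals left out, each in turn (highest 0.67). These 7 lists held 0 members past the threshold adjusted over the list alone. Of the 13 list calls, 5 held with each animal left out: the MHC class I, glucocorticoid, cholesterol, endothelial and astrocyte lists. The MHC class I and glucocorticoid lists therefore did not move alone, and a different mix of cells or of RNA quality is not excluded for them.

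**Figure D4:**
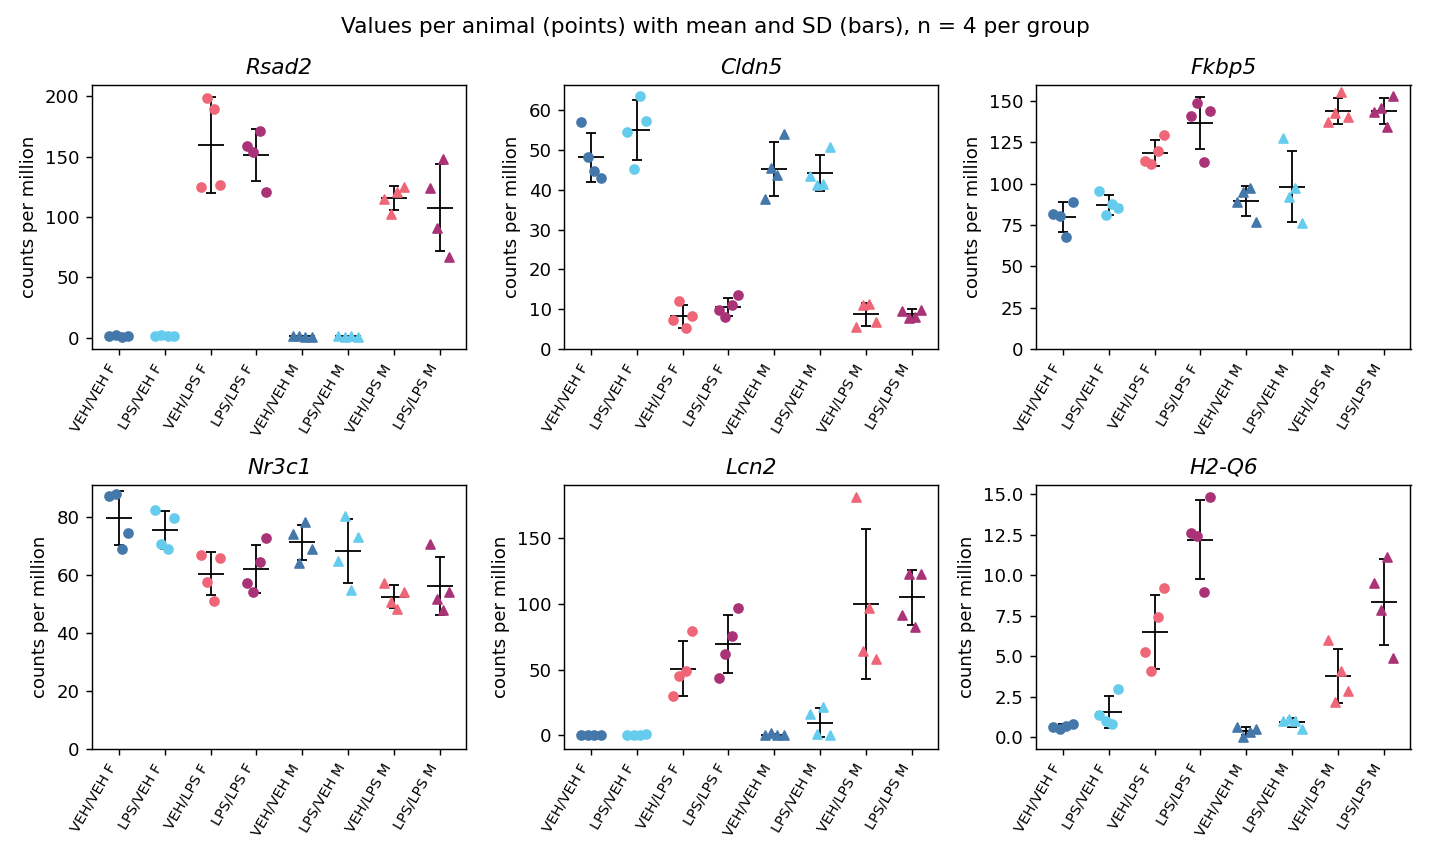
CPM (y, linear from 0) of 6 genes in the 8 groups (x, neonatal/adult treatment and sex); points are animals, and bars give the mean and SD, n = 4. Rsad2 averages 138 CPM in VEH/LPS and 1.295 in VEH/VEH over both sexes, and Cldn5 averages 8.40 and 46.7.

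Females and males were also taken one at a time (4 animals per group). After neonatal vehicle, adult LPS raised 330 and lowered 139 genes in females and raised 488 and lowered 161 in males. Both sexes shared 305 of the raised genes (9.7 expected if independent) and 91 of the lowered (1.4 expected). After neonatal LPS the counts were 394 higher and 158 lower in females and 475 and 123 in males, with 339 and 79 shared. With the 8 libraries left out, 320 genes passed in females and 409 in males after neonatal vehicle, and 536 and 538 after neonatal LPS. The fold changes of males and females had r = 0.911 over genes called in either sex after neonatal vehicle and 0.931 after neonatal LPS, with genes not independent replicates. The test of the difference between the sexes called 0 genes in edgeR after neonatal vehicle (511 at unadjusted p under 0.05) and 0 after neonatal LPS (506), and 0 in DESeq2. Predicted and RIKEN genes aside, the smallest p values were those of Ptafr (3.20; 2.49 without VEH/LPS male 8), Shld1, Hcls1, Anxa3 and Gpr12 after neonatal vehicle and of Fam129b, Cthrc1, Fam149a, Exoc6 and Mcmdc2 after neonatal LPS, all at adjusted p = 1.

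Neonatal LPS called 0 genes in edgeR in either sex. With adult vehicle, 1010 genes in females and 331 in males had an unadjusted p under 0.05, and 0 passed in DESeq2. Predicted and RIKEN genes aside, the smallest p in females belonged to Phf21b (0.88 ± 0.19, adjusted p = 0.606), and in males the 5 smallest included Hif3a (1.11 ± 0.28) and Lcn2 (4.61 ± 1.03, adjusted p = 1). For Lcn2 the value was 7.08 without VEH/VEH male 23 and 3.86 without LPS/VEH male 25, and it rests on 15.92 and 21.62 CPM in LPS/VEH males 2 and 25. With adult LPS the unadjusted counts were 284 in females and 931 in males, with 0 in DESeq2, and, predicted and RIKEN genes aside, the 5 smallest p in males included Foxo4 (0.49 ± 0.11). The interaction had 453 unadjusted in females and 334 in males, with 0 in DESeq2. Differences between the sexes in these effects also came to 0 in edgeR, with 565 (neonatal LPS with adult vehicle), 532 (with adult LPS) and 344 (interaction) at unadjusted p under 0.05. DESeq2 called 1, 0 and 0.

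Males and females were compared over all treatments (16 animals each). Genes of the Y and X chromosomes led. Kdm5d (chromosome Y, 897788 to 956786) and Uty, a pair of Y-linked demethylase genes, had 12.1 ± 1.38 and 5.76 ± 1.59 CPM in males (SD, n = 16) and 0 counts in females. Eif2s3y stood at 7.83 ± 1.08 CPM in males and had 10 counts in females, all in VEH/VEH female 20 (0.4141 CPM), with 0 in the other 15, and Ddx3y at 24.3 ± 3.02 CPM against 3 counts over all females. Xist (chromosome X, 103460366 to 103483254), the RNA that silences the inactive X, had 10.9 ± 4.63 CPM in females and 3 counts over all males. The X-linked Eif2s3x (-0.57 ± 0.06), Kdm6a (-0.44 ± 0.08; over the alternatives adjusted p = 0.00021 to 0.072, the highest with library date as a covariate), Ddx3x (-0.32 ± 0.05) and Kdm5c were lower in males. In all, 4 genes were higher and 16 lower in males, and 1367 had an unadjusted p under 0.05. Autosomal genes lower in males included Kdr (-0.41 ± 0.07, adjusted p = 0.002), and Tek (-0.48 ± 0.10, adjusted p = 0.0456) and the interferon-induced GTPase Tgtp2 (-1.27 ± 0.23, adjusted p = 0.00597), which had adjusted p = 0.0038 to 0.26 and 2.8e-05 to 0.26 over the alternatives, the highest without the 8 libraries. The call of Tek ended in 29 of 43 alternatives and that of Tgtp2 in 2. With those left out, 14 genes passed.

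As lists, 18 were called between the sexes with the preset correlation, 7 higher and 11 lower in males, and 0 with an estimated correlation. With 1 animal left out in turn, 15 of the 18 stayed called each time, and the calls that ended were cholesterol synthesis, oligodendrocytes and fibroblasts. Endothelial markers were lower in males (2 of 14 past the threshold, 7 adjusted over the list alone; adjusted p = 2.6e-07, adjusted p = 0.0755 with an estimated correlation), as were interferon-stimulated genes (0 of 35, 15 adjusted over the list alone; 3.52e-06, adjusted p = 0.17 with an estimated correlation) and homeostatic microglia genes (0 of 16, 4 adjusted over the list alone; 5.89e-08, adjusted p = 0.102 with an estimated correlation). The glucocorticoid list was higher in males (4 higher and 1 lower of 22 adjusted over the list alone; adjusted p = 0.000131, adjusted p = 0.102 with an estimated correlation). Fry, which asks whether a list moves on balance one way, called 4 lists: endothelial markers, tight junctions, pericytes and homeostatic microglia. CA1 markers were lower and CA2 and CA3 markers higher in males (adjusted p = 2.18e-06 and 5.46e-06; adjusted p = 0.17 and 0.138 with an estimated correlation). Other lists of cells and RNA quality differed in the same comparison. Higher in males were oxidative phosphorylation (2.45e-05), neutrophils and monocytes (5.43e-05) and blood erythroid cells (5.85e-05), along with heat shock (2.45e-05) and cholesterol synthesis (0.0148). Lower were pericytes (1.81e-06), astrocytes (0.000114), oligodendrocyte precursors (0.000117), oligodendrocytes (0.0019) and fibroblasts (0.0133), along with MHC class I (1.04e-05) and tight junctions (2.72e-05). A different mix of cells, more blood or RNA quality is therefore not excluded for the sex differences of lists.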

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

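The 13 measures checked for single far animals and the term for the 8 libraries were chosen only after the result was seen, and the tests of the integrity, GC content and depth of these libraries and the splits before. In 15 of 100 groups tested, 1 animal lay far from the other 3 of its group. Chance alone does so in about 1 in 20 groups if values are normally distributed. The CPM tested here were not log-transformed and are skewed for genes such as Ttr, so that rate need not hold. It does not apply at all to 4 of the 15, where the other 3 animals had 0 counts and any count would stand apart. That leaves 11 of the other 96 groups, a share that decides nothing about chance. Ttr, the main transcript of the choroid plexus, stood at 234.1 CPM in LPS/VEH male 25 (others 0 to 1.426), 1328 in LPS/LPS male 21 (1.21 to 56.87), 25.83 in LPS/VEH female 31 (0.2648 to 3.24) and 825.3 in LPS/LPS female 22 (0.4323 to 2.032). High values were not limited to animals given LPS as pups: VEH/VEH female 27 had 789.2 CPM, VEH/VEH female 26 had 137.2 and VEH/VEH male 34 had 146.7, in groups whose spread kept them from standing apart by this rule. Lcn2 stood at 1.424 CPM in VEH/VEH male 23 (0 to 0.1296) and 0.6703 in LPS/VEH female 31 (0 to 0.1059). S100a8 stood at 0.3691 CPM in VEH/VEH male 23 (0 to 0.04321) and 16.22 in VEH/LPS male 8 (0.8758 to 1.489), and Tap1 at 24.44 CPM in LPS/LPS male 21 (15.22 to 16.02). Xist stood at 22.4 CPM in VEH/LPS female 37 (6.621 to 7.211) and 20.32 in LPS/LPS female 36 (9.77 to 11.37), and at 0.09786 in LPS/LPS male 3 and 0.05152 in VEH/LPS male 28, where the other males of the group had 0. Females 36 and 37 are the 2 libraries without a date, and both are among the 8. In VEH/VEH females, 2 of them also among the 8, Xist was at most 11.1 CPM. Ddx3y stood at 0.09489 CPM in VEH/LPS female 6 and 0.04803 in LPS/LPS female 36, where the other females of the group had 0.

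Genes below the count filter were compared between the 16 adult LPS and the 16 adult vehicle libraries by two-sided permutation tests over 35 genes. The cytokine Tnf had 80 counts against 1, with counts in 14 of 16 LPS animals (permutation p = 1e-05, the smallest the draws can give; adjusted p = 0.00035). The chemokines Cxcl2 had 42 against 0 (adjusted p = 7e-04) and Ccl7 174 against 8 (adjusted p = 0.000817), with 102 without VEH/LPS male 8 and all 8 in VEH/VEH female 26. Il6 had 34 against 1 (adjusted p = 0.00639), and Mmp8, a neutrophil collagenase, 91 against 3 (adjusted p = 0.0103), with 33 without VEH/LPS male 8 and all 3 in LPS/VEH female 31.

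With the preset correlation, lists differed between the sexes in their response to adult LPS after neonatal vehicle (11 lists) and after neonatal LPS (9), and in their change with neonatal LPS given adult vehicle (4) and adult LPS (6). The interaction called 8 lists. With an estimated correlation 0 lists were called in each, with smallest adjusted p of 0.0684, 0.774, 0.96, 0.937 and 0.933.

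The 8 libraries with names ending in -R or without a date differed from the other 24 in 1625 higher and 1372 lower genes, and they came from all 4 treatments. Mitochondrially encoded genes were higher in them (7 of 11), nuclear oxidative phosphorylation genes more often lower (20 of 39) than higher (2), ribosomal protein genes too (12 of 44 lower, 2 higher), and 12 of 35 glutamate and GABA receptors were higher and 1 lower. Lower RNA integrity is argued against, since 87.1% of these genes stayed called with RIN as a covariate and mean RIN was 9.04 against 8.77, and depth is argued against by a ratio of median totals of 1.01. GC content and transcript length, which could reflect a different preparation, explained 11.35% of the variance across genes, between the bounds set beforehand, and stay open. Over the called genes alone they explained 25.75%, a share that was not set against the bounds. Among the called genes, higher ones had a median GC of 42.1% and length of 4622.5 bases, lower ones 54.7% and 2092.5. No biological explanation was tested.

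Each contrast was refitted on its own libraries for other splits of the same animals (35 for adult or neonatal LPS within a sex, otherwise 100, the real split included), so that the real counts differ from those of the fit to all 32 libraries. Chance is an unlikely source of the adult LPS counts, where only the real split reached its own value (1 of 100 or 1 of 35). Within a sex only 35 splits exist, so 1 of 35 is the smallest share they can give. Over both sexes the real split called 787 genes against at most 191 in another split after neonatal vehicle, and 932 against 2 after neonatal LPS. In females it called 372 against 0 and 593 against 1, and in males 474 against 392 and 425 against 118. The split that called 392 had an uneven share of the 8 libraries, 0.75 more in 1 group than in the other, and 409 genes were called in these males without the 8. For sex the real split called 20 genes and the next highest 3. Where the real split called 0 genes, every split reaches as many by construction (100 of 100 or 35 of 35), so these counts decide nothing about chance, and only the highest of the other splits is given. For the sex difference of the adult response the highest other was 735 after neonatal vehicle and 74 after neonatal LPS. For neonatal LPS with adult vehicle it was 2 over both sexes, 12 in females, 353 in males and 3 for the sex difference, and with adult LPS 55, 12, 66 and 229. For the interaction it was 397, 55, 311 and 10. Splits that call many genes where the real one calls 0 point to a structure of the samples. Those with 735 and 311 genes set the 8 libraries against the others as fully as any split drawn, and those with 353 and 397 did not.

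For counts of lists, splits were run for the 5 contrasts over both sexes only, so those for sex, within a sex and for sex differences have no test against chance here. With the preset correlation chance cannot be excluded in any of the 5. After neonatal vehicle the real split called 15 lists, the highest other 20, and 28 of 100 splits as many. After neonatal LPS these values were 14, 22 and 61, for neonatal LPS with adult vehicle 8, 18 and 64, with adult LPS 13, 20 and 48, and for the interaction 8, 17 and 67. With an estimated correlation, 8 lists were called after neonatal vehicle against at most 6 in another split, and 9 after neonatal LPS against 0.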

How the results depend on the processing

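The term for the 8 libraries, the fit without them and the Ttr covariate were chosen only after the result was seen. Counts of genes changed by adult LPS stayed within 1.5 times the reported value in most alternatives: over both sexes 667 to 1004 after neonatal vehicle (829 to 915 with 1 animal left out) and 885 to 1043 after neonatal LPS (851 to 953). In males after neonatal vehicle they fell to 405 without the libraries with names ending in -R and to 409 without the 8, where fewer samples remain, and were 553 to 666 with 1 animal left out. Genes differing between the sexes numbered 20, and 50 with DESeq2, 34 with library date as a covariate and 13 without the libraries with names ending in -R (14 to 27 with 1 animal left out). For the first 2 the cause was not tested. The sex difference of neonatal LPS with adult vehicle called 0 genes, and 1 with DESeq2, with the term for the 8 libraries and without LPS/VEH male 9 (0 to 1 with 1 animal left out). That gene was Gm12715, chosen after its values were seen (log2 -1.23, adjusted p = 0.264; adjusted p = 0.016, 0.0397 and 0.0401 in the 3), and the cause was not tested. The other neonatal and interaction counts and the other sex differences stayed at 0 in all 43 alternatives. With an estimated correlation, 0 lists were called for neonatal LPS with adult vehicle, neonatal LPS with adult LPS and the interaction. Fry also called 0 lists in each of these over both sexes (smallest fry adjusted p = 0.999, 0.389 and 0.959). It called 13 lists in each adult LPS contrast over both sexes. For neonatal LPS with adult vehicle, the 6 lists became 13 with the term for the 8 libraries and 3 with the Ttr covariate (3 to 9 with 1 animal left out, 3 without VEH/VEH female 26 or LPS/VEH male 35). For neonatal LPS with adult LPS the 13 became 9 to 17 with 1 animal left out. For the interaction, the 8 became 15 without the libraries with names ending in -R and 13 without the 8 (4 to 10 with 1 animal left out). It was 4 without LPS/LPS female 18 or male 21 and 5 without LPS/LPS female 17 or 22, VEH/LPS male 8 or female 37, or LPS/VEH female 10. The correlation of male and female responses across genes was 0.8568 after neonatal vehicle without the libraries with names ending in -R and 0.9558 in a fit to the groups of that contrast alone (0.8686 to 0.9228 with 1 animal left out). After neonatal LPS it was 0.9469 in that fit (0.9139 to 0.9289 with 1 animal left out). Beyond fewer samples or groups the cause was not tested. With the preset correlation, the list calls that held with each animal left out were 13 of 15 after neonatal vehicle, 14 of 14 after neonatal LPS, 2 of 6 for neonatal LPS with adult vehicle, 5 of 13 with adult LPS, 2 of 8 for the interaction and 15 of 18 for sex. No named gene reversed. Over all alternatives, 15 of 169 named genes lost and 10 gained a call for adult LPS after neonatal vehicle, 6 and 17 of 167 after neonatal LPS, and 7 and 14 of 161 for sex. No paired analysis by animal was possible because each animal number occurs in 1 group, and litter could not be taken into account. Depth limits genes such as Tnf, with 80 counts over 16 libraries, to a comparison of counts.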

Other observations

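The 3 tests of the Lcn2 values, the averaged neonatal contrast and the term for the 8 libraries in it were chosen only after the result was seen. Genes below the count filter were not part of the fits. Among them the brain aromatase Cyp19a1, which makes estradiol, had 20 counts over the 16 adult LPS libraries and 20 over the 16 adult vehicle libraries (two-sided permutation test, adjusted p = 0.955 over the 35 genes tested), and the mineralocorticoid-protecting enzyme Hsd11b2 had 7 and 5. Of the adrenal steroid enzymes, Cyp11b1 and Cyp11b2 had 0 counts in all 32 libraries, which allows up to 3 counts over them.

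Lcn2 was higher in a pair of males given LPS as pups and vehicle as adults than in all other vehicle animals. Male 2 had 15.9 CPM and male 25 had 21.6 CPM, whereas the other 14 vehicle animals of both neonatal treatments had 0 to 1.42 CPM and the lowest adult LPS animal had 30.2 CPM. A mislabelled adult LPS animal is argued against, since over 273 genes raised by LPS the higher of the animals' median positions between vehicle (0) and LPS (1) was 0.037, and carry-over of reads is too, with a median position of -0.004 relative to Lcn2. Blood neutrophils are argued against by S100a8 and S100a9, which together reached 0.0338 of the Lcn2 level. A candidate explanation that stays open and untested is another stimulus in these animals, such as stress: their glucocorticoid list scores were -0.349 and -0.194 against -0.738 to -0.477 in the other vehicle animals. Their reactive astrocyte scores, in a list that holds Lcn2, were -0.386 and -0.069 (others -0.82 to -0.159), and their interferon, NF-kB and endothelial activation scores lay within the range of the others. Male 2 had a blood erythroid score of 1.497 (others -0.569 to 0.597) and 260 CPM of Hbb-bs (others 64.1 to 141), so more blood in that sample stays open, whereas male 25, with more Lcn2, had 0.448 and 121 CPM.

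H2-Q6 (ENSMUSG00000073409; GRCm38 chromosome 17, 35424850 to 35430055) was higher in animals given LPS as pups when the effect was averaged over adult treatments and sexes (5.76 against 2.84 CPM, log2 1.13 ± 0.20 SE, n = 16 each, edgeR adjusted p = 0.0729). With a term for the 8 libraries the difference was 1.26 ± 0.21 (adjusted p = 0.0216), so their uneven share does not account for it, and of 16548 genes 0 passed without the term and 1 with it (993 and 861 at unadjusted p under 0.05). Reads lost to H2-Q6 by related class I genes are argued against, because the other H2-Q genes summed to 3.521 CPM more in the same animals, not less. Their sums were 17.5 against 14 CPM, and the SD of the sum's change over relabellings was 1.281. Reads of rising H2-Q genes counted as H2-Q6 would also give a joint rise. Sharing of reads in that direction was not tested and stays open. Chance is not excluded: 5 of 100 labellings of the neonatal treatment, the real one among them, gave a smallest adjusted p as low (lowest other 0.00986). A lasting effect of neonatal LPS on H2-Q6 may therefore be followed up only as a hypothesis.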
